A study of Rattus norvegicus with 2 samples.

How the data were processed

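Cartilage of Lewis rats had been profiled by single-cell RNA sequencing in 2 libraries. The first came from control rats without treatment. The second came from rats given type II collagen in complete Freund's adjuvant (collagen-induced arthritis, CIA) and collected on day 14. Per the labels' protocols, the tissue was dissociated with a warmed enzyme mix, and the libraries were made with the Chromium 3' kit, version 2. The values deposited by the authors were raw UMI counts per gene and cell (a UMI, unique molecular identifier, marks 1 captured RNA molecule), in 1 matrix per library, with Ensembl gene identifiers and symbols. Per the submitters' processing notes, the genome build was mRatBN7.2; the aligner, the counting tool, the calling of cells and the strand setting are not given in the sources used here. In both matrices every listed gene had at least 1 count and no cell had fewer than 4365 UMIs, so genes and cells had been filtered before deposit. The barcodes were 24 bases long, made of 3 blocks of 8 bases with 96 distinct blocks at each place, a structure that differs from the single block of the kit the labels name. Of the symbols, 2336 (control) and 2168 (CIA) were contig names of an earlier rat assembly. How many animals went into each library, and which joint and which pieces of it were taken, are not given in the sources used here.

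The control matrix held 5456 barcodes, 19726 genes and 76927821 UMIs, and the CIA matrix 8622 barcodes, 19250 genes and 105752977 UMIs. The median per cell was 11873 UMIs (range 5095 to 81453) and 2752 genes in the control library, and 10541 UMIs (4365 to 83311) and 2608 genes in the CIA library. Cells were kept with at least 200 genes and at most 20% mitochondrial UMIs, which removed 45 control and 47 CIA cells, all by the mitochondrial limit. Scrublet marked 65 control cells (1.20%) and 159 CIA cells (1.85%) as doublets, and these were removed, which left 5346 and 8416 cells. Gene models of mitochondrial ribosomal RNA held 2.63% and 1.46% of UMIs and did not count as mitochondrial. The 18147 genes listed for both libraries entered the comparisons, and the 1579 genes listed only for the control library and the 1103 listed only for the CIA library were set aside.

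Cells of both libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were taken, and Leiden clustering ran at resolution 0.5 on 15 nearest neighbours. Cells were handled with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, python-igraph 0.11.9, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, plots were drawn with matplotlib 3.10.9, and TMM factors came from edgeR 4.0.16 in R 4.3.3. Clusters were named from marker lists of 23 cell types fixed before the data were examined (183 of 198 markers were found in the files). A name needed at least 3 of its markers in 50% or more of the cluster's cells and was refused where another type had at least 2 markers, and more than the named type, among the 10 genes of highest fold; this scoring rule was set after the clusters had been seen. A cluster with at least 3 cell cycle markers among those 10 genes was named proliferating. Clusters 3, 5 and 8 stayed unnamed. Cluster 0 passed as fibroblast, but had 0 fibroblast markers and 1 marker of another type among the 10, so it is given by number without that name. A class was compared as a class only if none of its clusters had more markers of another class than of its own among those 10 genes, and otherwise its clusters were compared by number. Proliferating cells, which can be of several types, and unnamed clusters were compared by number in any case. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals. Because leading genes of some classes differed between the libraries within the class, the cells were also clustered without those genes, a step added after the data were seen.

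With 1 library per group no test was possible, and none was run: no difference has a replicate check, and every comparison is of those libraries, not of the conditions. Raw UMIs were summed over the cells of each library and class and scaled by the total of the genes listed for both, as CPM. The ratio of CIA to control CPM carries an exact conditional 95% interval. All intervals cover counting error only, not the spread between cells or animals. Genes with at least 100 UMIs over both sums were measured, and a gene was counted as higher or lower by a fixed rule of size, a ratio of at least 2-fold whose interval lay wholly beyond 1.5-fold. Where 1 library had 0 UMIs, the fold was computed against a floor of 3 counts in that library's sum and is given as "at least". Classes or clusters with at least 100 cells per library were compared, and the chondrocyte-like class (330 and 24 cells) and all kept cells were compared in any case.

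Gene lists of 23 themes had been fixed before the data were examined (444 of 461 members were found): cartilage collagens, proteoglycans and cartilage matrix proteins, fibrous matrix, chondrogenic regulators, hypertrophy, matrix-degrading proteases, protease inhibitors, cytokines and chemokines, NF-kB targets, interferon response, antigen presentation, complement, hypoxia and glycolysis, oxidative phosphorylation, redox and iron handling, unfolded protein response, immediate-early genes, heat shock, cell cycle, apoptosis and senescence, TGF-beta and BMP signalling, Wnt signalling, and lysosome and autophagy. For each list, members with at least 20 UMIs gave a median log2 ratio (CIA minus control), whose percentile was taken among 10000 random lists of the same size matched on mean CPM in 20 bins. The percentile describes these libraries and is no test. Genes were named by a rule fixed before the data were examined. In the chondrocyte-like class these were the 12 higher and 12 lower genes whose interval bound nearest to 1 lay farthest from 1; there were 8 each way over all cells, 5 each way in the other classes and up to 4 members of each list. Ribosomal, mitochondrial, haemoglobin and immunoglobulin genes and models without a symbol were left out of that choice. Col2a1, Acan and Prg4 are given in any case. Genes of near-identical families, such as the defensins and the MHC (RT1) genes, may be split differently by different counting tools, so their single values are uncertain.

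The size rule was tested on simulated counts drawn from the gene proportions of both libraries summed, with 200 genes changed by known folds. In the simulation of the chondrocyte-like comparison (3519 genes), 1 of 3319 unchanged genes met the rule, and the rule found 0% of genes changed 1.5-fold, 34% of those changed 2-fold, 66% at 3-fold and 84% at 5-fold. For all cells (12824 genes), 1 of 12624 unchanged genes met it, and it found 0%, 44%, 100% and 100%. The intervals held the true ratio for 96.4% and 95.5% of genes. Of 200 random gene lists in each comparison, 5.0% and 4.5% fell outside the central 95% of their matched lists. The simulation held counting error alone, so real cells vary more.

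The alternatives fixed before the data were examined were a minimum of 500 genes per cell, a mitochondrial limit of 10%, doublet calls kept, a Leiden resolution of 1.0, genes centred per library before the principal components, clustering without ribosomal, mitochondrial and immediate-early genes, TMM factors, total counts without the 50 most abundant genes and without ribosomal and mitochondrial genes, a minimum of 30 UMIs per gene, cells thinned to 5000 UMIs, equal weight for each cell, and genes left out whose CPM in another class of the same library was over 5 times that in the chondrocyte-like cells. Added after the data were seen were clustering without the leading genes that differed, comparisons within cluster 6 or cluster 14 alone, the chondrocyte-like class without cells in which over 1% of UMIs came from macrophage markers, and a count of other classes' genes whose CPM in the chondrocyte-like cells was over 5 times that in the class. Genome sequence and positions were not used here.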

Results

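Single-cell RNA sequencing was done on cartilage of Lewis rats, a strain used as a model of inflammatory arthritis. A control library came from untreated rats, called sham in the series' own design text, and a second library came from rats with collagen-induced arthritis (CIA), in which immunisation with type II collagen, the main collagen of cartilage, leads to joint inflammation. The CIA rats had received collagen and adjuvant before collection on day 14. There was 1 library per group, with 76927821 UMIs in 5456 control cells and 105752977 UMIs in 8622 CIA cells, at a median of 11873 and 10541 UMIs per cell. After filtering, 5346 control and 8416 CIA cells remained. The series title names articular chondrocytes, the cells that make and keep cartilage matrix, so the comparisons ask which cells the libraries held and how the RNA of the chondrocytes and of the cells around them differed between the control and the CIA library. With 1 library per group no difference could be tested or has a replicate check. Each value compares those libraries, not the conditions, and every 95% interval covers counting error only.

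Most cells of both libraries were not chondrocytes. Chondrocyte-like cells, with cartilage matrix genes such as Col2a1 and Chad, made up 6.17% of the control library (330 of 5346 cells, interval 5.54 to 6.85%) and 0.285% of the CIA library (24 of 8416 cells, 0.183 to 0.424%), a 21.6-fold lower share. Macrophage- or monocyte-like cells, of which 41.7%, 46.3% and 41.4% had a UMI of the complement genes C1qa, C1qb and C1qc that lead cluster 6 of the class, took 17.2% (918 cells, 16.2 to 18.2%) of the control and 32.6% (2744 cells, 31.6 to 33.6%) of the CIA library. Endothelial-like cells, the lining of blood vessels, took 12.3% (656 cells, 11.4 to 13.2%) and 6.39% (538 cells, 5.88 to 6.94%). Cells like those of the superficial cartilage zone or of the synovial lining, which make the lubricant Prg4, took 8.10% (433 cells, 7.38 to 8.86%) and 11.8% (990 cells, 11.1 to 12.5%). B-lineage-like cells with the precursor gene Vpreb1 numbered 84 in the control library (1.57%, 1.26 to 1.94%) and 1 in the CIA library (0.0119%, 0.000301 to 0.0662%).

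Among the rare classes, osteoclast-like cells, which resorb bone, took 0.580% (31 cells, 0.394 to 0.822%) of the control and 1.06% (89 cells, 0.850 to 1.30%) of the CIA library. Neutrophil-lineage-like cells took 0.599% (32 cells, 0.410 to 0.844%) and 0.891% (75 cells, 0.702 to 1.12%), with overlapping intervals, and pericyte- or smooth-muscle-like cells 0.430% (23 cells) and 0.428% (36 cells). Proliferating cells (5.97% and 9.76%), a class of dividing cells with fibroblast markers in cluster 2 and macrophage markers in cluster 15, were compared as clusters only. So were the fibroblast-like cluster 4 (19.6% and 10.7%) and cluster 0 (11.7% and 16.1%), which had detected fibroblast markers but was led by Sectm1b, Cbln1 and Sectm1a. The 3 unnamed clusters took 15.8% and 9.99%. These were cluster 3, led by the granule genes Ctsg, Elane and Mpo, cluster 5, led by Bglap, Chi3l1, Acan and Ucma, and cluster 8, led by haemoglobin genes.

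Of the 10 genes that led the chondrocyte-like cluster, 7 differed in size between the libraries within it, as did 13 of 30 for the macrophage-like class, 11 of 19 for the lining-like class and 0 of 10 for the endothelial-like class. With the differing genes left out of the clustering, a setting chosen after seeing the data, the chondrocyte-like shares were 6.38% and 0.285%, the macrophage-like 20.3% and 33.8%, the lining-like 7.76% and 11.5%, and no B-lineage cluster formed once its own 10 leading genes were left out. Without any clustering, 343 control cells (6.42%, 5.77 to 7.11%) and 44 CIA cells (0.523%, 0.380 to 0.701%) had a Col2a1 level of at least 1000 CPM, as did 0.638% and 0.250% of the cells outside the class. The order of the macrophage-like shares turned with a minimum of 500 genes per cell (18.1% and 16.5%), where a cluster of 151 control and 1548 CIA cells led by Spp1 and Ccl24 among others took no name, and with doublet calls kept the lining-like shares were 19.1% and 22.5%.

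**Figure D1:**
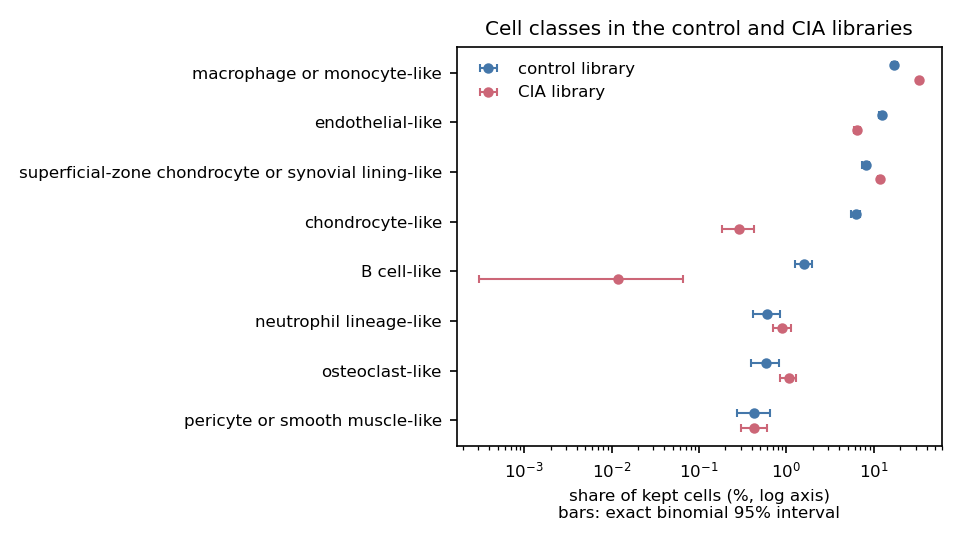
Share of cells per class (percent of the kept cells of a library, log axis) in the control library (5346 cells) and the CIA library (8416 cells), with exact 95% binomial intervals that cover counting error only. The chondrocyte-like share was 6.17% in the control and 0.285% in the CIA library.

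Within the chondrocyte-like class, genes of some matrix proteins and of proteases were among those higher in the CIA library. Spp1, the bone matrix protein osteopontin, was 7.10-fold higher in the CIA library (6.73 to 7.49), the collagenase Mmp13 4.95-fold (4.41 to 5.54) and the stromelysin Mmp3 4.31-fold (3.95 to 4.71). Mmp3 is among the genes left out when those over 5 times higher in another class of the same library are removed (120 higher and 175 lower genes then). Also higher were the adhesion-modulating glycoprotein Tnc 5.08-fold (4.21 to 6.12), the matrilin Matn4 5.89-fold (4.28 to 8.02) and the protease inhibitor Slpi 6.43-fold (5.59 to 7.38). Lower in the CIA library were the stress-response genes Atf3 (18.2-fold, 12.7 to 27.0), Dnajb1 (18.3-fold, 8.84 to 45.5), Hspb1 (7.63-fold, 6.63 to 8.83) and Btg2 (7.52-fold, 6.0 to 9.55). The chaperone Cryab was 55.2-fold lower (9.88 to 2185), with UMIs in 53 of 330 control cells and 1 UMI in the CIA cells. Other lower genes were the BMP antagonist Grem1 (26.0-fold, 11.1 to 80.1) and the cartilage proteins Cilp (9.13-fold, 6.72 to 12.7) and Cytl1 (7.47-fold, 5.88 to 9.63). Agt, the angiotensin precursor, was 104-fold lower (18.7 to 4116, 1 UMI in the CIA cells). Myoc was 20.4-fold lower (6.94 to 98.9, 3 UMIs), with UMIs in 86 of 330 control cells (26.1%) and 3 of 24 CIA cells (12.5%). The intervals count UMIs, not cells. For Cryab and Myoc, held by a small part of the control cells, 24 CIA cells leave the fold and its direction across cells uncertain. Tnni2, a troponin of fast muscle, and G0s2, an inhibitor of fat breakdown, had 1249 and 287 UMIs in the control cells (in 54 and 96 of 330 cells) and 0 in the CIA cells, at least 31.5-fold and 7.23-fold lower. Of the 3519 genes measured, 142 were higher and 198 lower in the CIA library by the size rule, in 330 control cells with 3391295 UMIs and 24 CIA cells with 256245 UMIs.

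Of the marker genes of articular cartilage, Col2a1 and Acan differed less than these. Col2a1 (ENSRNOG00000058560), the chain of type II collagen, was 1.38-fold lower in the CIA library (1.34 to 1.42), and Acan (ENSRNOG00000028992), the core of the large cartilage proteoglycan, was 1.48-fold higher (1.30 to 1.69). Prg4 (ENSRNOG00000002385), the joint lubricant, was 5.71-fold lower (5.18 to 6.31), while its median per-cell level was 957 CPM in the control and 792 CPM in the CIA cells. Single cells carried much of some higher genes: 42.2% of the CIA UMIs of Spp1, 47.9% of those of Mmp13, 43.7% of those of Mmp3 and 36.4% of those of Slpi came from 1 cell each, and without that cell the folds were 4.46, 2.67, 2.58 and 4.35. Single cells also carried much of what the CIA cells held of lower genes, among them Atf3 (50%), Btg2 (48.7%), Cilp (53.7%), Cytl1 (42.6%), Grem1 (40%), Frzb (61.9%), Bmp2 (40%), Hmox1 (42.9%) and Gadd45b (38.0%). Without that cell they were 35.4-fold, 14.2-fold, 19.2-fold, 12.7-fold, 41.9-fold, 17.1-fold, 12-fold, 5.12-fold and 6.53-fold lower. The cell was taken from the CIA sum alone, which enlarges the fold of a lower gene nearly by construction. These larger folds are therefore no check of the lower genes, and no control cell was left out in the same way. The median of all genes moved by -0.18 (log2) with TMM factors and by -0.12 without the 50 most abundant genes; the share of higher genes among those past the size rule was then 21.1% (68 higher, 254 lower) and 25.8% (80 and 230) in place of 41.8%.

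A larger part of the chondrocyte-like cells of the CIA library had a high level of Col1a1. Col1a1, the chain of the type I collagen of bone and scar, was 2.47-fold higher (2.43 to 2.52), at a median per-cell level of 1408 CPM in the control and 23070 CPM in the CIA cells. At limits set after the values were seen, 55 of 330 control cells (16.7%, 12.8 to 21.1%) and 14 of 24 CIA cells (58.3%, 36.6 to 77.9%) had at least 10000 CPM of Col1a1, against 1.22% and 0.372% of endothelial-like cells, which should lack it. At least 1000 CPM of Chad, an adhesion protein of cartilage and 1 of the genes that define the cluster, was found in 282 control cells (85.5%, 81.2 to 89.1%) and 10 CIA cells (41.7%, 22.1 to 63.4%), against 0% of endothelial-like cells in both libraries. In the control library 17 of 330 cells passed both limits, too small a part for the 0 of 24 CIA cells to tell a difference. The class thus held cells with different levels of Col1a1 and Chad in each library. A different mix of kinds of cells cannot be told apart from a difference of expression within the same kind, here or in the summed values. Median depths were 8483 and 9561 UMIs in the chondrocyte-like and 11355 and 8759 UMIs in the endothelial-like cells.

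**Figure D2:**
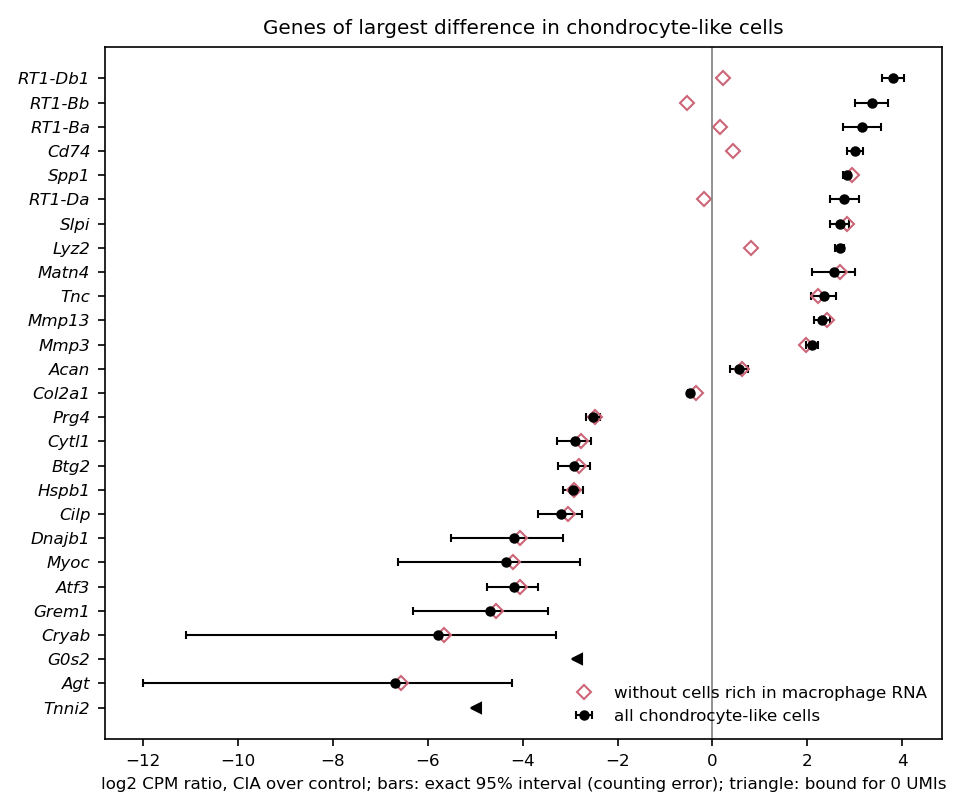
Log2 ratio of CPM (CIA over control) in the chondrocyte-like cells (24 CIA and 330 control cells) for the genes named by the fixed rule and for Col2a1, Acan and Prg4. Points carry exact 95% intervals for counting error, triangles mark the bound for genes with 0 UMIs in the CIA cells (Tnni2 and G0s2), and diamonds give the ratio without the 3 cells rich in macrophage RNA, where the class II genes come close to 0.

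Genes of MHC class II, which present antigen to T cells, were also higher in the summed chondrocyte-like cells of the CIA library, but their excess lay in 1 cell. RT1-Db1 was 14.0-fold higher (11.9 to 16.4), RT1-Bb 10.2-fold (8.01 to 13.1), RT1-Ba 8.86-fold (6.69 to 11.7), RT1-Da 6.87-fold (5.54 to 8.48), the invariant chain Cd74 8.03-fold (7.11 to 9.07) and the macrophage lysozyme Lyz2 6.43-fold (6.04 to 6.83). Of the 429 Cd74 UMIs in the CIA cells, 382 (89.0%) came from 1 cell, in which 5.53% of all UMIs were of macrophage markers, against a median of 0.169% in the chondrocyte-like and 7.83% in the macrophage-like cells of that library. Without the 3 cells (1 CIA, 2 control) in which such markers passed 1%, a setting chosen after seeing the data, Cd74 was 1.36-fold, RT1-Db1 1.17-fold, RT1-Ba 1.11-fold and Lyz2 1.77-fold higher, and RT1-Bb 1.44-fold and RT1-Da 1.14-fold lower. The antigen presentation list had 7 of 11 measured members at least 2-fold higher (median 1.90, percentile 100), and without those cells 0 of 11 (median 0.24, percentile 44.0). The complement list had 6 of 11 members higher, among them C1qb (7.19-fold, 4.23 to 12) and C1r (2.11-fold, 1.67 to 2.63), with a median of 1.08 (percentile 99.9), and without those cells 2 of 10 (median 0.44, percentile 78.9). Without the cell with most of each gene's UMIs, C1qb was 2.22-fold higher (0.846 to 4.95) and C1r 1.90-fold (1.47 to 2.41). With these 3 cells left out, 110 genes were higher and 170 lower. Cd74 was close to equal in the libraries with a minimum of 500 genes per cell, with a mitochondrial limit of 10% and with genes centred per library before clustering. It lay at -0.024, -0.023 and -0.025 on the log2 scale. The RT1 genes named above lay below their control level in these settings, with no interval given.

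Matrix genes of the chondrocyte-like cells differed by type. Of 13 measured genes of fibrous matrix, 4 were higher in the CIA library and 0 lower (median 0.69, percentile 99.0), with Col3a1 at 2.85-fold (2.73 to 2.98) and Col5a1 at 2.12-fold (1.70 to 2.62, and 1.88-fold without the cell with most of its UMIs). Of 11 cartilage collagen genes, 3 were higher and 1 lower (median 0.46, percentile 86.8). The higher ones were Col12a1 (3.36-fold, 2.94 to 3.83), Col6a2 (3.07-fold, 2.82 to 3.35) and Col6a1 (2.84-fold, 2.47 to 3.25), chains of collagens that many connective tissues share, and the lower one was Col9a2 (4.73-fold, 3.22 to 7.27), a collagen more specific to cartilage. Among 21 proteoglycans and cartilage matrix proteins 3 were higher and 8 lower, with a median of 0.00 (percentile 28.2). Proteases that break down matrix had 4 of 17 members higher and 0 lower (median 0.54, percentile 94.7), with the cathepsin Ctsk at 2.14-fold (1.74 to 2.61, and 1.92-fold without the cell with most of its UMIs) beside the metalloproteases. The other higher member, Ctss, was 10.3-fold higher with 75% of its CIA UMIs in 1 cell, and 2.85-fold (1.15 to 6.15) without it, which does not meet the size rule. Without the 3 cells rich in macrophage RNA 3 of the 17 were higher. Of 11 protease inhibitors 2 were higher, Timp1 (3.79-fold, 3.48 to 4.13, and 2.5-fold without the cell with most of its UMIs) and the collagen chaperone Serpinh1 (2.12-fold, 1.98 to 2.28), and Cst3 was lower (3.04-fold, 2.90 to 3.20), with a median of -0.28 (percentile 3.55). The hypertrophy list, of genes active before cartilage turns to bone, held both Spp1 and Mmp13, which were higher, and had a median of -0.27 (percentile 5.67). The osteoblast protein Bglap, also on it, had 280 UMIs in the control cells and 0 in the CIA cells, but those lay in 26 of 330 control cells (7.88%), too small a part for 0 of 24 CIA cells to give a direction.

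Lists of chondrogenic regulators, of TGF-beta and BMP genes and of stress genes lay low in the summed chondrocyte-like cells of the CIA library. A possibly different makeup of the class limits these sums as well. Chondrogenic regulators had 4 of 11 members lower and 0 higher (median -1.26, percentile 0; -0.49 with genes at 0 UMIs set to their bound). They included Sox9, the main transcription factor of chondrocytes (2.42-fold lower, 1.81 to 3.31), its partner Sox5 (11.6-fold, 2.06 to 463, 1 UMI in the CIA cells) and Zbtb20 (3.32-fold, 1.51 to 9.14). Immediate-early genes, which respond within minutes to stress and to tissue dissociation, had 19 of 23 members lower (median -2.05, percentile 0), among them Klf4 (6.67-fold, 4.51 to 10.3) and Ier2 (6.44-fold, 4.45 to 9.72). Heat-shock genes had 6 of 11 lower (median -1.71, percentile 0), with the co-chaperone Bag3 at 8.40-fold (4.06 to 21.0). In the TGF-beta and BMP list 6 of 19 were lower (median -0.68, percentile 0.01), among them Bmp2 (7.42-fold, 3.16 to 23.0), while the activin subunit Inhba was 4.16-fold higher (3.11 to 5.51), with 59.1% of its CIA UMIs in 1 cell, without which it was 1.76-fold higher (1.13 to 2.63). Wnt genes had 3 of 12 lower, the secreted antagonists Frzb (7.08-fold, 5.23 to 9.84), Sfrp5 (13.1-fold, 3.61 to 109, 2 UMIs) and Wif1 (2.26-fold, 1.97 to 2.61), at a median of -0.14 (percentile 7.03), within the central 95% of random lists. The apoptosis and senescence list had 6 of 16 lower (median -0.62, percentile 0.1), including Gadd45b (4.16-fold, 3.29 to 5.34) and Cdkn1a (3.34-fold, 2.01 to 6.01).

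Inflammatory gene lists were not higher in these cells. Cytokines and chemokines had 2 of 14 lower and 0 higher (median -0.61, percentile 0.27), namely Il1b (243 UMIs in 62 control cells and 0 in the CIA cells, at least 6.12-fold) and the neutrophil attractant Cxcl1 (10.05-fold, 3.90 to 37.0). NF-kB targets had 3 of 16 lower, among them Nfkbia (6.19-fold, 4.27 to 9.34) and Icam1 (4.49-fold, 2.16 to 11.2), and 1 higher, the secreted glycoprotein Chi3l1 (2.60-fold, 2.45 to 2.75), with a median of -0.07 (percentile 18.0). Without the 1 cell that held 35.1% of its CIA UMIs, Chi3l1 was 1.79-fold higher (1.67 to 1.92). Only 7 interferon-response genes were measured (median -0.44, percentile 7.69; 0.29 with genes at 0 set to their bound), with Irf1 23.9-fold lower (4.25 to 946, 1 UMI in the CIA cells) and Psmb9 3.93-fold higher (1.81 to 7.88). Without the 1 cell that held 45.5% of its CIA UMIs, Psmb9 was 2.37-fold higher (0.816 to 5.65).

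Of the metabolic lists, hypoxia and glycolysis genes had 2 of 22 lower, among them Vegfa (4.02-fold, 2.02 to 9.38), at a median of -0.40 (percentile 0.07). Within the central 95% of random lists, oxidative phosphorylation had 1 of 23 higher, Ndufa4 (2.09-fold, 1.72 to 2.52; 1.97-fold without the cell with most of its UMIs), at a median of 0.50 (percentile 94.2). Redox and iron genes had Nqo1 higher (4.35-fold, 2.62 to 6.98) and 2 of 21 lower, Hmox1 (3.04-fold, 1.80 to 5.59) and Sod3 (2.07-fold, 1.73 to 2.51), with a median of -0.05 (percentile 10.3). Without the 1 cell that held 45.8% of its CIA UMIs, Nqo1 was 2.60-fold higher (1.32 to 4.72), which does not meet the size rule. Without the 3 cells rich in macrophage RNA 0 of the 21 genes were higher. The unfolded protein response had 0 of 20 past the size rule (median 0.23, percentile 42.3), and lysosome and autophagy genes 2 of 20 higher, Ctsz (3.28-fold, 2.07 to 5.03) and Npc2 (2.14-fold, 1.73 to 2.62), and 1 lower (median 0.26, percentile 48.1). Of the CIA UMIs of Ctsz 81.5% came from 1 cell, without which it was 1.49-fold lower. Npc2 was 1.37-fold higher without the cell that held most of its UMIs. Without the 3 cells rich in macrophage RNA 0 of the 20 genes were higher. Of 13 cell cycle genes 1 was lower, Pcna (4.05-fold, 2.40 to 7.45); the list's median was -1.51 (percentile 2.88), and 0.10 with genes at 0 UMIs set to their bound.

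**Figure D3:**
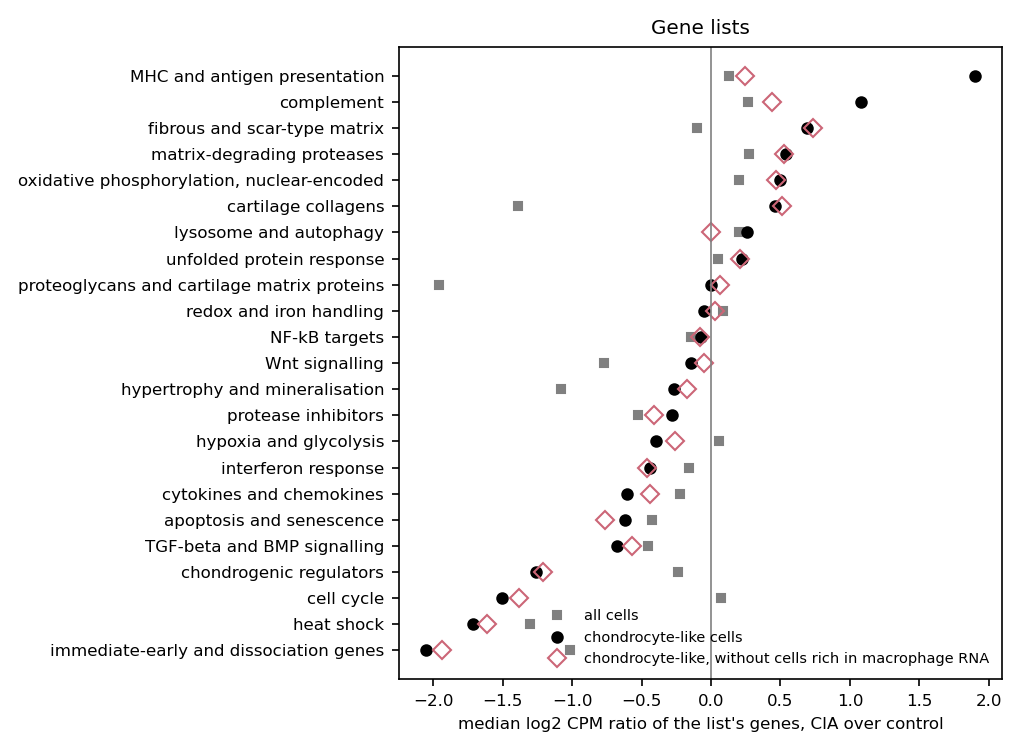
Median log2 ratio of CPM (CIA over control) of each of the 23 gene lists over all cells (squares), in the chondrocyte-like cells (points) and in the chondrocyte-like cells without the 3 cells rich in macrophage RNA (diamonds). Immediate-early genes had the lowest median in the chondrocyte-like cells (-2.05), and the antigen presentation median was 1.90 with those cells and 0.24 without them.

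Over all kept cells, where differences of cell makeup and of expression are summed, cartilage genes were far lower in the CIA library. Chad was 71.1-fold lower (66.6 to 75.9), the cytokine-like Cytl1 77.8-fold (65.5 to 93.1), the chondromodulin Cnmd 90.7-fold (54.7 to 163), Col9a2 75.1-fold (53.6 to 109), Clec3a 49.3-fold (44.4 to 54.8) and Snorc 44.5-fold (41.2 to 48.0). The osteoblast protein Bglap was 52.2-fold lower (44.6 to 61.6), and Igll1, a part of the B-cell precursor receptor, 706-fold (195 to 5841, 2 UMIs in the CIA library). Col2a1 was 20.1-fold lower (19.6 to 20.7) and Acan 1.49-fold lower (1.43 to 1.54), while Prg4 was 1.62-fold higher (1.61 to 1.63). Higher in the CIA library were genes of granulocytes and mast cells, namely the eosinophil protein Prg2 (7.01-fold, 4.64 to 11.1), the mast cell protease Cma1 (6.42-fold, 3.68 to 12.1) and the defensins Defa11 (5.98-fold, 4.63 to 7.83), Defa5 (4.52-fold, 4.33 to 4.71) and RatNP-3b (3.57-fold, 3.47 to 3.68). So were the eosinophil attractant Ccl24 (5.01-fold, 4.53 to 5.55), the gelatinase Mmp9 (4.29-fold, 4.16 to 4.43) and Amtn (24.2-fold, 10.9 to 66.7). By the size rule 104 of 12824 measured genes were higher and 545 lower.

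The lists followed the same division over all cells. Cartilage collagens (median -1.39, percentile 0, 6 of 11 lower), proteoglycans and cartilage matrix proteins (-1.96, percentile 0, 14 of 23 lower) and hypertrophy genes (-1.08, percentile 0, 8 of 15 lower) were low. Wnt genes (-0.77, percentile 0), TGF-beta and BMP genes (-0.45, percentile 0) and chondrogenic regulators (-0.24, percentile 1.97) were low as well, with Sox9 3.16-fold lower (2.97 to 3.38). Immediate-early genes (-1.01, percentile 0, 13 of 25 lower), heat-shock genes (-1.30, percentile 0, 6 of 12 lower) and apoptosis and senescence genes (-0.42, percentile 0) were low too, with Hsph1 at 3.94-fold (3.84 to 4.04). Matrix-degrading proteases (0.27, percentile 100), complement (0.26, percentile 100), oxidative phosphorylation (0.20, percentile 99.8) and lysosome genes (0.20, percentile 99.8) lay high, with 1 of 20 proteases, 1 of 17 complement genes and 0 of 23 and 0 of 20 genes of the last pair of lists higher by the size rule. Ctsk was 1.88-fold higher (1.86 to 1.89) and C5ar1, the receptor of a complement fragment, 2.11-fold (2.06 to 2.17). Antigen presentation (0.13, percentile 96.9), redox (0.08, 87.9), cell cycle (0.07, 86.1), hypoxia (0.05, 80.0) and unfolded protein response (0.05, 73.1) lay within the central 95% of random lists. So did fibrous matrix (-0.10, percentile 9.79). Interferon response (-0.16, 2.45), cytokines (-0.22, 0.23), NF-kB targets (-0.14, 0.67) and protease inhibitors (-0.53, 0.01) lay below it.

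In the macrophage-like class the lists of NF-kB targets, cytokines and stress genes lay low in the CIA library. The NF-kB genes Nfkbiz (6.03-fold, 5.72 to 6.35), Birc3 (6.27-fold, 5.54 to 7.12) and Icam1 (5.19-fold, 4.92 to 5.47) were lower, as were Cxcl1 (4.13-fold, 4.01 to 4.26), Cxcl2 (3.13-fold, 3.06 to 3.20), Il1a (8.39-fold, 5.35 to 13.6) and the chaperone Hsph1 (11.5-fold, 11.0 to 12). Ccl24 (4.45-fold, 3.92 to 5.06), Gsg1 (11.7-fold, 5.27 to 32.4), Dmkn (6.46-fold, 3.03 to 16.5), the defensins Defa5 (10.5-fold, 8.02 to 13.9) and RatNP-3b (4.38-fold, 3.85 to 4.99), the fibronectin gene Fn1 (2.64-fold, 2.60 to 2.67) and Spp1 (2.43-fold, 2.41 to 2.45) were higher. Defa5 and RatNP-3b were abundant in the neutrophil-lineage-like cells (16643 and 29223 CPM). Whether RNA of those cells adds to them here was not tested. NF-kB targets had a median of -0.75, cytokines of -0.66, heat-shock genes of -1.60 and immediate-early genes of -1.20, all at percentile 0. Hypoxia and glycolysis genes had a median of 0.34 (percentile 100), with 0 of 23 members higher and 3 lower by the size rule, and Ldha at 1.96-fold (1.91 to 2.00). Matrix lists lay low as well, fibrous matrix at -0.32 (percentile 0.02, 1 of 13 higher), cartilage collagens at -2.32 (7 of 11 lower) and proteoglycans and cartilage matrix proteins at -1.86 (12 of 17 lower, 2 higher), the last pair at percentile 0. By the size rule 55 of 9426 genes were higher and 339 lower, in 918 control and 2744 CIA cells. Most control cells of the class (629) lay in cluster 1, which held 83 CIA cells and was led by Gdf15, Cd83 and Ccl4. Most CIA cells (1901) lay in cluster 6, with a further 760 in cluster 11. Within cluster 6 alone, 22 genes were higher and 68 lower, and the immediate-early and heat-shock medians were -0.18 and -0.33. There 0 of 25 immediate-early and 2 of 10 heat-shock genes were lower by the size rule. The other lists and the named genes are not given within 1 cluster. In the summed class, their differences cannot be told apart from the different mix of clusters. Cartilage genes led the lower list, with Chad 119-fold lower (67.9 to 232), and 40 of the 339 lower genes were over 5 times as high in the chondrocyte-like control cells as in this class.

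In the lining-like class the protease list lay high in the CIA library (median 0.22, percentile 100), with 1 of 20 members higher and 1 lower by the size rule. The protease inhibitor list lay low (-0.33, percentile 0.14), with 1 of 10 higher and 2 lower. Mmp3 was 1.77-fold higher (1.76 to 1.79) and Timp1 1.97-fold, both under the 2-fold of the size rule, Timp3 2.42-fold and the neutrophil attractant Cxcl3 3.44-fold (3.20 to 3.70). Larger folds were found for Lrat, an enzyme of vitamin A storage (8.96-fold, 7.48 to 10.8), Ccl5, a T-cell attractant (28.1-fold, 9.50 to 138), Cldn11 (8.55-fold), Gap43 (4.89-fold) and Amtn (41.4-fold, 7.26 to 1651, 1 UMI in the control cells). Prg4, a defining gene of this class, was 1.11-fold higher. Grem1, which was lower in the chondrocyte-like cells, was 2.40-fold higher here (2.14 to 2.69). Lower were Cst3 (2.82-fold), Il1b (3.11-fold), Ccl2 (2.40-fold) and 4 of 22 genes of the interferon response (median -0.64, percentile 0), among them Isg15 (3.22-fold, 2.41 to 4.33) and Bst2 (2.38-fold, 2.00 to 2.83). The 1 higher member of that list was Cxcl9 (5.45-fold, 2.40 to 15.3). Fibrous matrix (0.25, percentile 99.8, 0 of 14 past the size rule) lay high, and TGF-beta and BMP genes (-0.66) and immediate-early genes (-0.98) low, both at percentile 0. By the size rule 48 of 8664 genes were higher and 236 lower, in 433 control and 990 CIA cells, and 35 of the lower genes, such as Chad and Col2a1, were over 5 times as high in chondrocyte-like cells. Control cells lay in clusters 13 (210 cells) and 14 (223), CIA cells mostly in cluster 14 (965), and within cluster 14 alone 57 genes were higher and 76 lower. The immediate-early and heat-shock medians there were -0.69 and -0.26. The other lists and the named genes are not given within 1 cluster.

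In endothelial-like cells the lists of immediate-early genes, NF-kB targets and cytokines lay low in the CIA library. Il6 was 11.1-fold lower (6.62 to 20.2), Cxcl1 8.02-fold (7.16 to 9.01), Nfkbia 3.26-fold (3.12 to 3.41), the leukocyte adhesion gene Icam1 3.19-fold (2.88 to 3.53) and Atf3 6.16-fold (5.64 to 6.73). Immediate-early genes had 17 of 25 members lower (median -1.39), NF-kB targets 6 of 19 (-0.31) and cytokines 7 of 17, with 1 higher (-0.44), all at percentile 0. Cell cycle genes lay high (0.29, percentile 99.2, 0 of 19 past the size rule), with Mki67 1.41-fold (1.27 to 1.57) and Top2a 1.43-fold higher (1.28 to 1.61). The chemokine Cxcl6 was 3.14-fold higher (2.55 to 3.86) and Btnl9 2.89-fold (2.42 to 3.46). Apoc1 (7.27-fold, 4.77 to 11.5), Trem2 (3.41-fold, 2.62 to 4.46) and Spp1 (2.99-fold, 2.71 to 3.30), genes of macrophages, were higher as well, in a library in which macrophage-like cells took the larger share. By the size rule 31 of 8599 genes were higher and 127 lower, in 656 control and 538 CIA cells. Of the lower genes 27, among them Snorc (215-fold, 38.3 to 8506, 1 UMI in the CIA cells) and Chad (127-fold, 34.9 to 1050, 2 UMIs), were over 5 times as high in chondrocyte-like cells.

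The remaining clusters were compared by number. In cluster 0 Cxcl9 (6.16-fold, 3.85 to 10.4), Spp1 (3.54-fold, 3.21 to 3.91) and Mmp9 (2.19-fold, 1.73 to 2.82) were higher in the CIA library, and 18 of 8832 genes were higher and 59 lower. Mmp9 was at 9991 CPM in osteoclast-like cells against 19.3 CPM in all others, and Spp1 was abundant in macrophage-like clusters 6 and 11. Whether RNA of those cells adds to both genes in cluster 0 was not tested. Cluster 4, fibroblast-like, had 16 of 8750 higher and 86 lower, with Ccl12 3.77-fold and the cornea and tendon proteoglycan Kera 2.96-fold higher and Il1b 3.04-fold lower (2.43 to 3.84). Cluster 2, proliferating cells with fibroblast genes, had 37 of 8195 higher, among them the B-cell attractant Cxcl13 (3.27-fold, 3.07 to 3.48), and 102 lower, among them Il6 (6.83-fold, 5.21 to 9.07). Cluster 5, led by Bglap and Acan, had 12 of 7537 higher and 88 lower, and its hypertrophy list was low (median -0.56, percentile 0), with Bglap 38.4-fold (32.4 to 45.8), the mineralising phosphatase Alpl 5.10-fold (4.09 to 6.42) and the bone protein Ibsp 3.01-fold lower (2.67 to 3.40). Cluster 3, with granule genes, had 42 of 4171 higher and 68 lower, and cluster 8, with haemoglobin genes, 22 of 3171 and 209. Interferon genes lay high in both (0.27, percentile 99.4, 1 of 16 higher, and 0.44, percentile 99.9, 2 of 22 higher), with Isg15 15.1-fold higher in cluster 3 (8.44 to 29.3) and Cxcl10 1.81-fold higher in cluster 8 (1.31 to 2.5). Prg2 had 0 UMIs in the control and 214 in the CIA cells of cluster 3, at least 136-fold higher. Some lower genes of each cluster were over 5 times as high in chondrocyte-like cells. These were 16 in cluster 0, 21 in cluster 2, 7 in cluster 3, 21 in cluster 4, 21 in cluster 5 and 3 in cluster 8. Ibsp is also among the leading genes of the chondrocyte-like cluster.

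**Figure D4:**
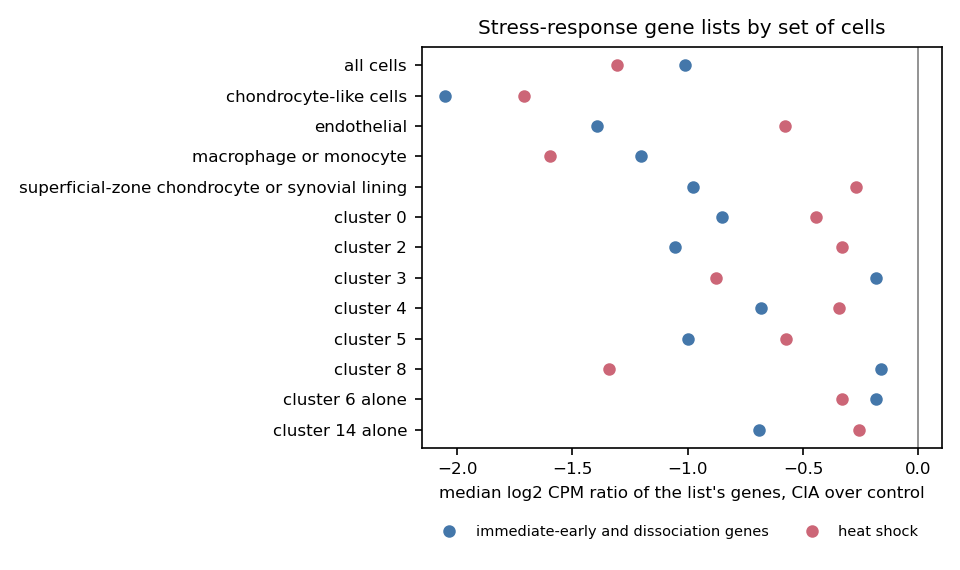
Median log2 ratio of CPM (CIA over control) of the immediate-early and heat-shock lists in each compared class or cluster, and in clusters 6 and 14 taken alone from the macrophage-like and lining-like classes. All plotted medians lie below 0, from -0.16 (cluster 8, immediate-early) to -2.05 (chondrocyte-like, immediate-early).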

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

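The genes in this part were picked out by fixed rules over all compared classes, and no explanation was tested for them. Among them, 4 genes passed the size rule in opposite directions in different cell classes, and the differences between the classes were not tested. Chi3l1 was higher in the CIA library in chondrocyte-like cells (log2 ratio 1.38) and lower in endothelial-like (-1.17) and lining-like cells (-1.13). Without the 1 cell that held 35.1% of its UMIs in the CIA chondrocyte-like cells, Chi3l1 was 1.79-fold higher there (1.67 to 1.92), under the 2-fold of the size rule. Its control level was 18.9 CPM in endothelial-like and 70.3 CPM in lining-like cells, against 2127 CPM in chondrocyte-like cells, so in those classes it is over 5 times higher in the chondrocyte-like cells, a class of far lower share in the CIA library. Cxcl3 was higher in lining-like cells (1.78) and lower in macrophage-like cells (-1.19). Grem1 was higher in lining-like cells (1.26) and lower in chondrocyte-like cells (-4.56). Prg4, abundant in lining-like cells, was higher in macrophage-like cells (1.11) and lower in chondrocyte-like cells (-2.51).

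Genes listed for 1 library only did not enter the comparisons, and those with the most UMIs lay above the 3 UMIs that a count of 0 allows in the other library. Only the control library listed Col10a1, the collagen of hypertrophic cartilage (53 UMIs), Krtap17-1 (40), Ptgds (38), the transcription factor Foxa2 (35) and the bone-derived peptide Ostn (27). Only the CIA library listed Gzma, a protease of cytotoxic lymphocytes (30 UMIs), Bmp8b (17), Cd207, a marker of Langerhans cells (16), Mal2 (12) and Krtap13-1 (8). All genes listed for the control library alone summed to 3215 UMIs and those listed for the CIA library alone to 1786 UMIs.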

How the results depend on the processing

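The tests chosen only after the results were seen are the clustering without differing leading genes, the comparisons within cluster 6 or 14 alone, the chondrocyte-like class without cells rich in macrophage RNA and the omission of genes over 5 times higher in chondrocyte-like cells. No paired analysis was possible because the results come from no test and each group has 1 library. The chondrocyte-like share stayed within its interval under all 7 other clusterings or filters (6.17 to 6.78% in the control, 0.241 to 0.297% in the CIA library). The counts of genes higher and lower over all cells stayed within 1.5 times under each alternative run (98 to 120 higher, 453 to 749 lower). Across all results, 104 gene counts stayed within 1.5 times and 28 moved, 43 shares stayed within their interval and 27 moved, and 297 values of named genes kept their size, 91 moved and 17 reversed. Of the list medians of the chondrocyte-like class and of all cells, and of the stress lists, 189 stayed, 4 moved and 3 reversed, and 153 others stayed. Depth limits the chondrocyte-like comparison, since 24 CIA cells held 256245 UMIs and the size rule found 66% of simulated 3-fold differences there, against 100% over all cells.

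The reversals all concern MHC class II in the chondrocyte-like cells, as log2 ratios. A reversal is a change of sign, also where the libraries were close to equal, as for Cd74. With genes centred per library the antigen presentation median was -0.025, Cd74 -0.025, RT1-Db1 -0.16, RT1-Bb -0.91, RT1-Ba -0.39 and RT1-Da -0.40. With a minimum of 500 genes these were -0.024, -0.024, -0.28, -0.70, -0.28 and -0.51, and with a mitochondrial limit of 10% they were -0.12, -0.023, -0.18, -0.43, -0.74 and -0.21. Without cells in which macrophage markers passed 1% of UMIs the median was 0.24, RT1-Bb -0.42 and RT1-Da -0.13; this setting leaves out the 1 CIA cell that held most class II UMIs, and for the other settings the cause was not tested. The immediate-early median of these cells was -1.67 with the 10% limit. Their count of higher genes was 68 with TMM factors, 80 without the 50 most abundant genes, 85 with the 10% limit and 90 with centred genes, and their count of lower genes was 116 with cells thinned to 5000 UMIs.

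Macrophage-like shares of the control and CIA libraries were 20.9% and 34.8% at resolution 1.0, 20.9% and 35.4% with doublet calls kept, 20.8% and 34.9% with centred genes, 21.0% and 34.8% with the 10% limit, 20.8% and 34.8% without ribosomal, mitochondrial and immediate-early genes, and 20.3% and 33.8% without differing leading genes. With 500 genes the CIA share was 16.5%, because a cluster of 1548 CIA cells took no name. Lining-like shares were 5.39% and 7.08% at resolution 1.0, 19.1% and 22.5% with doublets kept, where clusters otherwise named fibroblast or left unnamed took this name, 6.72% and 8.64% with centred genes, 5.60% and 8.91% with 500 genes, and 14.6% and 15.4% without ribosomal, mitochondrial and immediate-early genes. Endothelial-like shares were 10.1% and 5.48% with the 10% limit, which removes cells. B-lineage shares were 0% and 0% without the class's own leading genes. For the other shares the cause was not tested.

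A minimum of 30 UMIs measures more genes. It gave 377 lower genes in the lining-like class, 35 higher and 103 lower in cluster 0, 61 and 158 in cluster 2, 144 lower in cluster 4, 22 higher and 150 lower in cluster 5 and 40 higher in cluster 8. Thinning to 5000 UMIs, which leaves fewer counts, gave 18 higher and 76 lower in the endothelial-like class, 7 and 34 in cluster 0, 12 and 37 in cluster 2, 24 higher in cluster 3, 8 higher and 46 lower in cluster 4, 55 lower in cluster 5 and 12 higher in cluster 8. Within cluster 6 alone the macrophage-like comparison gave 22 higher and 68 lower genes, an immediate-early median of -0.18 and a heat-shock median of -0.33. Within cluster 14 alone the lining-like comparison gave 57 higher and 76 lower genes.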

Other observations

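The tests chosen only after the results were seen are the 3 on the chondrocyte-like share, the handling test of the stress genes and, for the class II genes, the Lyz2-based test and the ratio without cells rich in macrophage RNA. Hypoxia and glycolysis genes lay high in the CIA library in several groups: cluster 0 (median 0.17, percentile 99.9), fibroblast-like cluster 4 (0.25, percentile 100), proliferating cluster 2 (0.29, percentile 100), cluster 5 (0.20, percentile 99.4) and the lining-like class (0.28, percentile 100). By the size rule 0 of 23 members were higher in each of these, and 0, 1, 1, 1 and 2 were lower. The glycolytic genes Eno1 (1.31-fold, 1.27 to 1.35) in lining-like cells, Pgk1 (1.35-fold, 1.28 to 1.42) in cluster 4 and Aldoa (1.35-fold, 1.31 to 1.41) in cluster 2 were examples of these small differences. Adm, a vessel-dilating peptide on the same list, went the other way. It was 3.56-fold lower in lining-like cells (2.66 to 4.79), 4.96-fold lower in endothelial-like cells (4.20 to 5.90) and 3.28-fold, 3.20-fold and 4.70-fold lower in clusters 2, 4 and 5.

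Complement C3, the central protein of the cascade, was lower in the CIA library in clusters 2 (3.99-fold, 3.08 to 5.21), 4 (2.16-fold, 2.01 to 2.32) and 5 (3.03-fold, 2.45 to 3.78). The antioxidant enzyme Sod3 was 3.78-fold lower in endothelial-like cells (2.59 to 5.69) and 2.32-fold lower in macrophage-like cells (1.88 to 2.86). The chondrocyte-like cells had it 2.07-fold lower, from 970 CPM in the control. Whether RNA of those cells adds to Sod3 in the other classes was not tested. Fibrous matrix genes lay high in cluster 5 (median 0.22, percentile 100, with 0 of 14 members higher and 1 lower by the size rule), with Fbn1 at 1.52-fold (1.44 to 1.61) and Tnc at 1.39-fold (1.36 to 1.43). They lay low in the proliferating cluster 2 (-0.21, percentile 0.15), where Postn was 2.03-fold lower (1.97 to 2.09) and Fn1 1.90-fold higher (1.88 to 1.92). In cluster 0 the cytokine list lay high (0.25, percentile 100), although 0 of 18 members were higher and 1 lower by the size rule, with the neutrophil attractants Cxcl6 at 1.90-fold (1.85 to 1.95) and Cxcl3 at 1.54-fold (1.47 to 1.62).

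The share of chondrocyte-like cells was 21.6-fold lower in the CIA library. Placement of cells with high Col2a1 in other clusters is argued against as the whole cause. Of the CIA cells outside the class 0.250% (21 cells, beside 24 in it) had at least 1000 CPM of Col2a1. Chondrocytes low in Col2a1 would escape this count, so their placement elsewhere stays open. Unnamed cluster 5, with the chondrocyte markers Acan and Ucma among its leading genes, took 7.89% of the control and 5.83% of the CIA library. Whether it holds chondrocytes was not tested. Counted by Col2a1 alone, the shares were 6.42% and 0.523%, a 12.3-fold lower share in the CIA library, so the size of the difference depends on how chondrocytes are counted. Bursting of all missing chondrocytes in the suspension is argued against only if their freed RNA was captured with other cells. Col2a1 outside the class was at 10.7% (10.2 to 11.3%) of the control level, whole cells with high Col2a1 included (32 control, 21 CIA). Whether freed RNA was captured is not known, since the barcodes differ from those of the named kit. Bursting of a part of the chondrocytes stays open. A different piece of joint, or a different depth of digestion, stays open. The CIA-to-control share ratios of the other large named classes (at least 100 cells per library) spanned 3.64-fold. The smaller B-lineage-like class (84 control cells, 1 CIA cell) had a 132-fold lower share. The sources do not say which pieces were taken, and with 1 library per group this cannot be told apart from the disease. A loss of chondrocytes in arthritis stays open as well and was not tested.

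Immediate-early and heat-shock genes were lower in the CIA library. Scaling by total counts is argued against, since the immediate-early median over all cells was -0.98 at its highest under the other scalings. Different handling times or temperatures of the cells may account for the pattern, since the immediate-early median lay below 0 and under the central 95% of random lists in 10 of 10 classes or clusters. Within macrophage-like cluster 6 alone the medians were -0.18 and -0.33, so part of the difference in that class lay between its clusters. An effect of the disease on these genes stays open and was not tested.

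MHC class II genes were higher in the summed chondrocyte-like cells of the CIA library. Free RNA alone is argued against, since their CPM there was 7.13 times (median of the genes) the higher of the levels in CIA clusters 0 and 4. A few barcodes that mix several cells may carry this class II RNA, since 92.3% of the Cd74 UMIs lay in 3 cells. Whether the amount matches a chondrocyte and a macrophage under the same barcode cannot be told apart. The class II excess was 2.38 times that predicted from Lyz2, and the macrophage RNA of that barcode need not have an average makeup. Higher class II expression across the chondrocytes of the CIA library is argued against as the source of the excess, since the ratio of the summed genes was 9.25 (8.55 to 10) in all cells of the class and 1.14 (0.911 to 1.42) without the cells rich in macrophage RNA. A small difference within that interval stays open, as does class II expression by the 1 cell itself.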
